A study of Megalobrama amblycephala with 2 samples.

How the data were processed

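Gene expression was measured by RNA sequencing of liver from juvenile blunt snout bream (Megalobrama amblycephala), a freshwater cyprinid farmed in China. One library came from the group held at 35 °C for 72 h and 1 from the control group held at 25 °C for the same time. Per the labels' protocols, polyadenylated RNA was captured with oligo(dT) beads, fragmented and copied into paired-end libraries for an Illumina instrument. One sentence of the series' design text refers to nitrite concentrations, while the labels of both samples give only temperature, which defines the groups here. Livers were taken from more than 1 fish per group, and the labels do not say whether a library holds the RNA of 1 fish or of several. The sequencing protocol in the labels describes no strand marking.

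The authors deposited 1 table for the whole series, with 1 RPKM value per library for each of 35281 assembled transcript components. RPKM is the number of reads normalised to transcript length and to the mapped reads of the library, and the unit is taken from the file headers. Values carry 2 decimals. Bowtie, RSEM and edgeR are named in the submitters' processing notes without role or version. The assembler, the annotation and any filter on low values are not given in the sources used here. Each identifier holds a cluster number and a sub-component number, and the table lists the transcripts grouped under it. Components with the same cluster number are called an assembly cluster here, from the form of the identifiers alone.

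The table pairs no identifier with a gene name. None of the identifiers matched an entry of the RefSeq gene table for assembly ASM1881202v1 (0 matches against 38087 genes), and no component sequences were used here. The 32 gene lists fixed before the data were examined (23 pathways, such as heat shock proteins and antioxidant enzymes, and 9 sets of cell type markers) therefore could not be applied, and none has a result. For a table without names, the rule fixed at the same time names at most 2 components higher and 2 lower in the heat library, those with the most extreme log2 fold among components of at least 10 RPKM in at least 1 library. Genomic positions are not analysed here.

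With 1 library per temperature there is no test across samples, no standard error and no p-value. A fixed size rule took its place. Components with a mean of at least 1 RPKM over the 2 libraries entered, and the log2 fold was log2((heat + 1)/(control + 1)), with a pseudocount of 1 RPKM. That scale understates the change of components near or below the pseudocount. Components at least 2-fold apart on it were counted per direction. Every difference below is a difference between these libraries and has no replicate check.

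Read numbers are not in the table, so no counting interval is given. RPKM steps still carry the relative depth. Among 13491 components with a mean of 0.5 to 1.5 RPKM and at least 0.25 RPKM in each library, the log2 ratio of the libraries piled up at -0.059, with 402 components within 0.01 of that value against 53.5 expected from the surroundings. Components with equal read numbers in both libraries lie there, so the heat library held about 1.04 times the reads of the control library. The 95% bootstrap interval was 1.041 to 1.042 (200 resamples of components). Its ends are neighbouring steps of the search, so it shows the step size more than the error. In simulated data a true ratio of 1.04 was recovered as 1.038, an error wider than this interval. The absolute depth is unknown.

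Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The fold and depth calculations were tested on simulated data with 35281 components and 200 changed ones, at 4-fold or 8-fold. The changed ones were drawn from components with a mean of at least 10 RPKM, with counting noise alone at an assumed depth. All 200 (100%) were recovered as at least 2-fold apart in the right direction, and a simulated depth ratio of 1.04 was recovered as 1.038. Recovery at lower levels, of 2-fold changes or with differences between fish was not simulated. Alternatives were other pseudocounts (0.1 and 5 RPKM), other minimum levels, 3 rescalings of the heat library, a 4-fold threshold and, chosen after seeing the data, summing of assembly clusters, removal of components listed at 0 and, for the gap between level classes, plain log2 ratios without a pseudocount. The series' design text states a count of differentially expressed genes. The table holds no comparison columns of the authors, so no such comparison is reported and that count was not checked.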

Results

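Liver transcript levels were compared between 1 library from fish held at 35 °C for 72 h (the heat library) and 1 library from fish held at 25 °C (the control library). The comparison addresses which transcripts differ in liver after acute warming. Both libraries gave an RPKM value for the same 35281 assembled transcript components, and gene names were not used here because the table pairs none with its identifiers. RPKM values summed to 767855 in the heat library and 750651 in the control library. The median component stood at 1.83 RPKM in heat and 1.74 RPKM in control. In heat, 3622 components reached 10 RPKM, 557 reached 100 RPKM and 133 reached 1000 RPKM. The corresponding numbers in control were 3603, 593 and 121. There were no replicates, so no value below has an error estimate across fish, and none of the differences was tested.

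Most of the liver transcriptome lay within 2-fold between the temperatures. Of 29462 components with a mean of at least 1 RPKM, 25710 were less than 2-fold apart, 1955 were at least 2-fold higher in heat and 1797 were at least 2-fold lower. With the heat library rescaled by a trimmed mean of log ratios, 1712 were higher and 1924 lower, so the majority direction turned. It did not turn with the median ratio (1927 higher, 1809 lower) or the upper quartile (1873 higher, 1841 lower). The components at least 2-fold apart made up 12.7% of those compared. At least 4-fold differences were fewer, with 269 components higher and 259 lower in heat. The median log2 fold (heat over control) was 0.05, with quartiles at -0.33 and 0.41. Across components, the log2(RPKM + 1) values of the libraries correlated with Pearson's r = 0.88 and the RPKM values with Spearman's rho = 0.63. These are correlations across components, which are not independent replicates. The 2-fold counts depended on the pseudocount, since 3900 components were higher and 3430 lower with a pseudocount of 0.1 RPKM, against 356 and 399 with 5 RPKM.

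**Figure D1:**
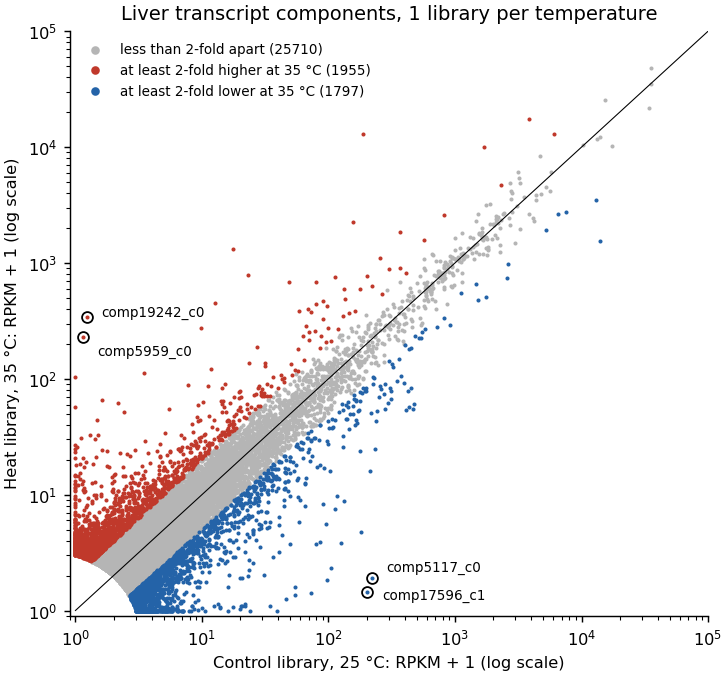
Each point is a transcript component with a mean of at least 1 RPKM, plotted by its RPKM + 1 in the control library (x axis, log scale) and in the heat library (y axis, log scale), with the line of equality. Red points (1955) were at least 2-fold higher and blue points (1797) at least 2-fold lower in the heat library, and circles mark the 4 named components, which lie far from the line at both ends.

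Ranked with the pseudocount of 1 RPKM, the most extreme components were below 1 RPKM in one library and well expressed in the other. The ranking rests on that pseudocount, as with 0.1 RPKM some components listed at 0 in one library pass some of them. The component comp19242_c0 stood at 341.15 RPKM in heat and 0.23 RPKM in control, a log2 fold of 8.12. The component comp5959_c0 stood at 227.82 RPKM in heat and 0.14 RPKM in control, a log2 fold of 7.65. In the other direction, comp17596_c1 stood at 0.45 RPKM in heat and 202.35 RPKM in control, a log2 fold of -7.13. The component comp5117_c0 stood at 0.90 RPKM in heat and 219.83 RPKM in control, a log2 fold of -6.86. All 4 held a single assembled transcript. Their lower values can rest on few reads, so the size of each fold is imprecise. With pseudocounts of 0.1 and 5 RPKM, the log2 fold of comp19242_c0 ranged from 6.05 to 10.01 and that of comp5959_c0 from 5.50 to 9.89. That of comp17596_c1 ranged from -8.52 to -5.25 and that of comp5117_c0 from -7.78 to -5.25.

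The cluster of comp17596_c1 held 2 further sub-components, and both had lower values in heat. One of them was among the most abundant components of the control liver, at 13123 RPKM against 3478 RPKM in heat, a log2 fold of -1.92. The other stood at 31.7 RPKM in control and 20.1 RPKM in heat, a log2 fold of -0.63, which is less than 2-fold.

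Large differences also reached the most abundant transcripts. Of 677 components with at least 100 RPKM in at least 1 library, 65 were at least 2-fold higher in heat and 97 at least 2-fold lower, and 30 were at least 4-fold higher and 30 at least 4-fold lower. At least 16-fold differences were found for 9 higher and 5 lower components of this class. Membership by the higher value favours components with large folds. By a mean of at least 100 RPKM, 595 components held 52 at least 2-fold higher and 74 lower, and 24 at least 4-fold higher and 20 lower. Ranked by the value in the library where they were higher, the leading component at least 2-fold higher in heat stood at 3809 RPKM in control and 17481 RPKM in heat, 4.59 times as high in heat, and groups 29 assembled transcripts. The second in this ranking stood at 186 RPKM in control and 12960 RPKM in heat, 69.8 times as high in heat. It accounted for 1.69% of the summed RPKM in heat and 0.0247% in control. The leading component at least 2-fold lower in heat stood at 13926 RPKM in control and 1551 RPKM in heat, 8.98 times as high in control. Its share of the summed RPKM was 1.86% in control and 0.202% in heat.

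A few abundant components held much of the transcriptome in both libraries. The 10 most abundant components held 27.1% of the summed RPKM in heat and 26.9% in control, and the 100 most abundant held 57.9% and 57.3%. Of the 10 most abundant components, 7 were shared by the libraries, and of the 100 most abundant, 90 were shared. The component with the highest mean stood at 48239 RPKM in heat and 35149 RPKM in control, a log2 fold of 0.46. The component with the second highest mean differed little, at 34954 RPKM in heat and 35445 RPKM in control.

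The balance of higher and lower components differed in degree between expression levels. Among 25849 components with a mean of 1 to 10 RPKM, 1676 were at least 2-fold higher in heat and 1428 lower, so that 54.0% of the differing components were higher. Among 3486 components of 10 to 1000 RPKM, 270 were higher and 360 lower, so that 42.9% were higher. At 1000 RPKM or more, 9 of 127 components were higher and 9 lower. The share of components at least 2-fold apart was 12.01% at 1 to 10 RPKM, 18.1% at 10 to 1000 RPKM and 14.2% at 1000 RPKM or more. This order depended on the pseudocount, which shrinks the folds of low components: with 0.1 RPKM the shares were 25.6%, 19.6% and 14.2%. With the heat library rescaled by a trimmed mean of log ratios, the higher share was 49.9% at 1 to 10 RPKM and 38.3% at 10 to 1000 RPKM. Neither class then held a majority of higher components. Rescaling by the median ratio gave 53.5% and 42.3%, and by the upper quartile 52.6% and 41.0%. The higher share was thus larger at 1 to 10 RPKM under each rescaling.

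**Figure D2:**
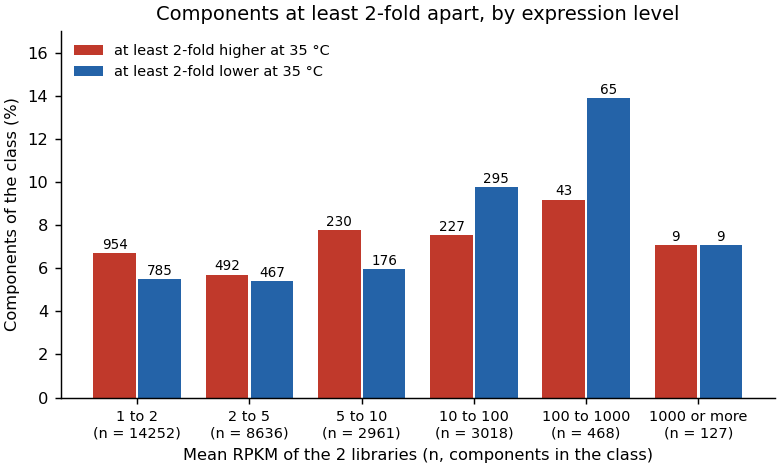
Bars give the percentage of components in each class of mean RPKM (x axis, with the number of components in the class) that were at least 2-fold higher (red) or lower (blue) in the heat library, with their number above each bar. Below 10 RPKM the higher components outnumbered the lower ones, as in 230 against 176 at 5 to 10 RPKM. From 10 to 1000 RPKM the lower ones outnumbered the higher ones, as in 65 against 43 at 100 to 1000 RPKM. Rescaling by a trimmed mean of log ratios brought the higher share at 1 to 10 RPKM to 49.9%. With the median ratio it was 53.5%, and with the upper quartile 52.6%.

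Components were also compared by the number of assembled transcripts they group. At a mean of 10 RPKM or more, 18.6% of 2096 components with 1 transcript were at least 2-fold apart, against 18.0% of 881 components with 2 to 4 transcripts and 15.7% of 636 components with 5 or more. In the same order, 177, 58 and 44 of these were higher in heat and 212, 101 and 56 lower. At 1 to 10 RPKM the shares at least 2-fold apart were 11.9%, 13.9% and 10.3%, another order than at 10 RPKM or more. In all 3 groups the share of differing components that were higher in heat was larger at 1 to 10 RPKM than at 10 RPKM or more. It was 53.5% against 45.5% with 1 transcript, 57.6% against 36.5% with 2 to 4, and 70% against 44% with 5 or more, where 20 components differed at 1 to 10 RPKM.

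Some components were listed at 0 in one library. In heat, 289 components were listed at 0 with a value above 0 in control, at a median of 2.13 RPKM there. In control, 371 components were listed at 0 with a value above 0 in heat, at a median of 1.97 RPKM there. Values of at least 10 RPKM opposite a 0 occurred for 14 components in heat, up to 102.88 RPKM, and for 3 components in control, up to 37.91 RPKM. A listed 0 can be a failed estimate, so no fold is printed for any of these components. With the pseudocount, 348 of them are among the components counted as at least 2-fold apart, and without components listed at 0 the counts were 1773 higher and 1631 lower.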

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

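The alternatives with summed clusters, without components listed at 0 and with plain log2 ratios for the gap between level classes were chosen after seeing the data, and the others before the data were examined. The main setting gave 1955 components at least 2-fold higher and 1797 lower in heat. The pseudocount moved both counts, to 3900 higher and 3430 lower at 0.1 RPKM and to 356 higher and 399 lower at 5 RPKM. A minimum mean of 10 RPKM left 279 higher and 369 lower among fewer components, and a 4-fold threshold left 269 and 259. Without a minimum level, under the 3 rescalings (median ratio, trimmed mean of log ratios, upper quartile), with clusters summed and without components listed at 0, both counts stayed within 1.5 times of the main ones. The majority direction was not stable. In the main setting, 52.1% of the differing components were higher in heat. The share was 47.1% after rescaling by the trimmed mean of log ratios and 43.1% at a minimum mean of 10 RPKM. After rescaling by the median ratio it was 51.6%, and by the upper quartile 50.4%. For the 4 named components, pseudocounts of 0.1 and 5 RPKM and rescaling by the median ratio bear only on the size of the log2 fold. A pseudocount shared by both libraries cannot turn the direction of a fold. The median ratio was a factor of 1.0047, too small to turn folds of this size. Gene list medians, summing by gene name, removal of ribosomal and mitochondrial RNA and counts from the authors' own comparison could not be run, because the table holds neither names nor comparison columns. Leaving out a replicate was not possible with 1 library per group. Without read numbers, the precision of single low values is unknown.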

Other observations

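The tests on level classes and on counting error in this part were chosen after the results were seen. Those of assembly clusters against shuffles, and on differences unrelated to temperature, were chosen before. The count of pairs that went the same way and the split of pairs at 10 RPKM were not among the tests chosen before.

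Sub-components of one assembly cluster tended to differ between the libraries in the same way. Over 4732 pairs from 2999 clusters, with a mean of at least 1 RPKM for both members, the log2 folds of the 2 members correlated with r = 0.58 across pairs. A like level alone gave no such correlation, as 1000 shuffles among components of like mean level gave at most r = 0.06. The median log2 fold differed little between level classes (-0.07 at 100 to 1000 RPKM to 0.06 at 5 to 10 RPKM). A like level could therefore hardly have given a correlation, and the shuffles exclude little else. The members also had closer levels than shuffled pairs, with a median difference of 0.59 log2 units against 0.93 in the closest shuffle. Pieces of one transcript, or read pairs that span pieces, could give this. Related genes with a shared response may give the same and stay open. The 3752 components at least 2-fold apart fall into 3547 clusters, and how many genes these are was not tested.

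Of 226 pairs in which both members were at least 2-fold apart, 218 pairs (96.5%) went the same way. The correlation was r = 0.64 for the 3925 pairs with both members under 10 RPKM and r = 0.58 for the 227 pairs with both members at 10 RPKM or more. It was thus not higher where counting error is smaller. Neither correlation has an interval, and the second rests on 227 pairs. The comparison therefore does not decide whether pieces of one transcript account for all pairs.

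The components at least 2-fold apart may have more than one source. Counting error of few reads is argued against for components of at least 100 RPKM, since counting error shrinks with level. There 21.2% were at least 2-fold apart against 13.7% at 5 to 10 RPKM (21.3% against 17.1% with a pseudocount of 0.1 RPKM). The excess lay at 100 to 1000 RPKM (23.1%, or 23.3% with 0.1 RPKM). At 1000 RPKM or more the share was 14.2% with either pseudocount, so for these components alone the comparison with 5 to 10 RPKM does not decide. For components of 1 to 10 RPKM, counting error remains a candidate explanation for part of the calls. There, with a pseudocount of 0.1 RPKM, the share at least 2-fold apart was 31.4% at 1 to 2 RPKM and 17.1% at 5 to 10 RPKM. Temperature and fish, tank or library differences unrelated to temperature cannot be told apart, because there was 1 library per group.

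The median log2 fold was higher among components of 1 to 10 RPKM (0.0504) than among those of 10 to 1000 RPKM (0.0066), a gap of 0.0438. One scaling factor adds the same amount to every plain log2 ratio, so on ratios without a pseudocount it can make no gap between classes. With the most abundant component of each cluster alone, that gap was 0.0627, against -0.0598 to 0.0406 in 1000 random assignments of components to classes. One factor is argued against by that algebra, while the random assignments address only whether a gap of this size arises by assignment. They do not allow for the choice of classes after the results were seen. The gap is small, and components are not replicates. It is no steady fall with level, as the median was 0.0148 at 10 to 100 RPKM, -0.0735 at 100 to 1000 RPKM and 0.0140 at 1000 RPKM or more. A response of some liver transcripts to warming, or a difference in background reads between the libraries, may underlie the gap, and neither was tested.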
